A study of Gallus gallus with 4 samples.

How the data were processed

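The series holds gene expression arrays of chorioretinal tissue, that is retina with the choroid behind it, from chicks. Per the labels' protocols, the right eye of each chick was covered with a glass goggle on day 6 after hatching, which induces myopia, and the left eye stayed uncovered as the control. The goggles were worn for 7 days in a cycle with 12 hours of light, under either normal or violet light, and tissue was collected on day 13 as buttons 6 mm wide from the back of the eye, temporal to the optic nerve. The design text counts 16 eyes of 8 chicks, and RNA of 4 eyes was mixed into 1 pool per group. Each pool was labelled with Cy3 from 100 ng of RNA and hybridised to 1 of the 4 arrays of a single slide. The titles call the tissue retina, while the protocol describes a chorioretinal button.

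Per the file headers and the submitters' processing notes, the scans were read with Agilent Feature Extraction 11.5.1.1 in 1 colour. The deposited scanner files give an intensity per spot, background-subtracted and detrended by that program and not scaled between arrays, with 0 or 1 marks (another unit, as deposited) for saturation, outlier spots and signal well above background. The authors' value table holds linear intensity values whose 4 columns share nearly the same distribution, with column medians of 218.39, 218.57, 218.35 and 218.67. How the table was normalized is not given in the sources used here. Set against the scanner files, the table is linear, is not centred per gene and runs in the same direction.

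Each table column was compared with each scanner file over all probes on the log2 scale. Columns labelled uncovered violet light and covered normal light matched their own scanner files, with correlations of 0.99962 and 0.9995 across probes. The column labelled uncovered normal light matched the scanner file of the covered violet-light pool (0.99921) better than its own (0.98151). The column labelled covered violet light matched the scanner file of the uncovered normal-light pool (0.99974) better than its own (0.98178). The labels of these 2 arrays are thus crossed between the 2 deposited sources. All values below follow the scanner files' labels unless the table's labels are named, and every comparison was repeated with the table's labels.

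Signals were processed in R 4.3.3 with limma 3.58.1 and in Python 3.11.15. Of 43803 spots that are not controls, repeated spots of one probe were averaged to 43603 probes, and 26 of these with an outlier mark on any array were left out of the comparisons. Values are log2 of the processed signal minus the array's 75th percentile of it. Probes were named through an unversioned match of their RefSeq accession to RefSeq genes of assembly GRCg7b. This gave 11711 probes 1 gene symbol, none several, and left 31892 without a name here, 14881 of them because they carry Ensembl transcript identifiers. The named probes cover 5294 genes. The files state an older chicken build than the reference, so no coordinates are given. A probe entered the comparisons where it was well above background on all 4 arrays and saturated on none. That left 35407 probes, 10418 of them named, for 4807 genes. Each gene is represented by its passing probe with the highest mean signal, and 3125 genes had at least 2 passing probes.

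Each group is 1 array, so a difference between 2 groups has no replicate check and no p-value. Genes are counted where the log2 difference reached 1 in size, which is 2-fold. A gene was also counted where it passed in the same direction in both lights, or in both eyes. For the goggles alone, a limma fit of light and goggles (lmFit and eBayes, 1 residual degree of freedom, Benjamini-Hochberg threshold 0.05) used the eyes of one light as a pair, on the assumption that goggles act alike in both lights. No such fit was made for light, which separates 2 sets of chicks. On simulated arrays for 4807 genes with 200 changed, that fit recovered 99% of 4-fold changes with 5 false calls and 0% of 2-fold changes. In the same simulation, 27.5% of the genes changed 2-fold reached 2-fold in both lights, as did 6 unchanged genes. The simulated goggle change was the same in both lights. In the measured arrays, the goggle difference was at least 2-fold higher under violet than normal light for 34 genes and lower for 119. The simulated recovery of 4-fold changes thus does not describe the fit on the measured arrays.

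For each of 34 gene lists, the median difference is given with its percentile among the medians of 10000 random lists of equal size, matched on mean signal in 20 bins. These percentiles describe these arrays and are no test of the conditions. The named genes are EGR1, and the 10 higher and 10 lower genes with the largest smaller-of-2 difference for goggles and for light. They also include the 8 most positive and 8 most negative genes for the difference between lights in the goggle contrast, and 5 in each direction for each pair of pools. To these come up to 4 members with the largest mean difference per list. Not every gene that met these rules is named in the text, but all are in the counts and medians. Genes well above background on both arrays of one side and on neither of the other have only a lower bound of the fold, up to 5 per side. That bound sets the bright side's mean against the higher of the dim probe's own signal and the array's lowest signal well above background. The groups, tests, lists, naming rule and alternatives other than those named below as later were fixed before the data were examined.

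The alternatives were quantile normalization, median scaling, cyclic loess, normexp background correction (offset 50), the authors' value table, 3 other filters on dim probes and the mean of a gene's probes. For the limma fit, a variance trend and a model without light were added. The normexp correction was to use the mean spot signal, which the deposited scanner files lack, so it used the median spot signal with its background. Chosen after the data were seen were the repeat with the table's labels, the table put on the scanner files' labels, and the counts without the striated muscle and lens lists. No group has a further array, so no array could be left out.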

Results

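Gene expression was measured in 4 pools of chick chorioretinal tissue, each made of RNA from 4 eyes and read on 1 array. The pools were uncovered eyes under normal light, uncovered eyes under violet light, goggle-covered eyes under normal light and goggle-covered eyes under violet light. The eyes of one light came from the same chicks, while the lights separate 2 sets of chicks. No group has a replicate array, so the differences below have no error between animals, and the number of arrays limits their precision. Among 43 probes printed 5 times and well above background, the SD of a log2 difference between 2 arrays was 0.04, which covers spot error alone.

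The share of probes well above background was 85.97% in the uncovered normal-light pool, 84.43% in the uncovered violet-light pool, 83.75% in the covered normal-light pool and 83.07% in the covered violet-light pool. No spot was saturated. The 75th percentile of the processed signal was 2108, 1325, 797.5 and 883 in the same order, so both covered pools were dimmer before scaling. Across probes, the uncovered normal-light array correlated least with the others (0.9773 with covered normal light, 0.9783 with covered violet light and 0.9878 with uncovered violet light), against 0.9896 to 0.9943 among the other arrays.

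The direction of every value below depends on which of the 2 deposited sources carries the right labels. The authors' value table and the scanner files give opposite labels to the arrays here called uncovered normal light and covered violet light. Differences that are covered minus uncovered under the scanner labels become normal minus violet light under the table's labels, in covered eyes for the normal-light pair and in uncovered eyes for the violet-light pair. Differences that are violet minus normal light under the scanner labels become uncovered minus covered, under violet light for the uncovered pair and under normal light for the covered pair. The light-by-goggle difference has the same value under both.

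**Figure D1:**
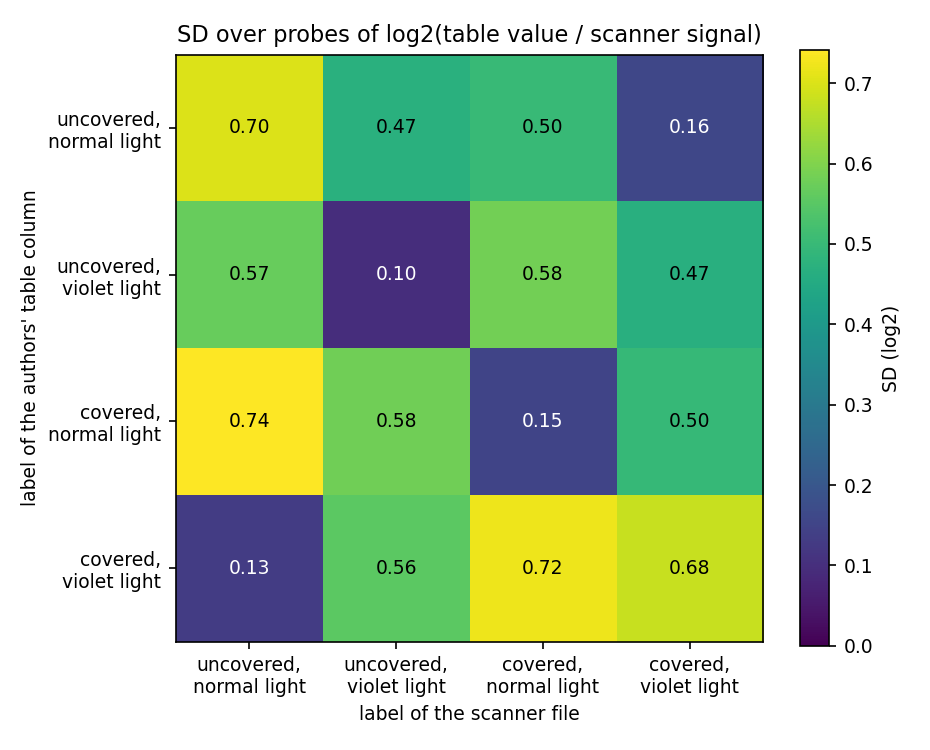
Standard deviation over probes of the log2 ratio between each column of the authors' table (vertical axis) and each scanner file (horizontal axis); low values mean a match. The columns labelled uncovered normal light and covered violet light lie at 0.16 and 0.13 from each other's scanner file and at 0.70 and 0.68 from their own, while the other columns lie at 0.10 and 0.15 from their own.

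The first question was what a goggle did to the chorioretina, whatever the light. EGR1, an immediate-early transcription factor whose retinal level is known to follow the direction of eye growth, was lower in covered eyes under normal light (log2 difference -1.44, 2.72-fold) and under violet light (-1.22, 2.33-fold). Among opsins, the red cone pigment OPN1LW was higher in covered eyes by 1.51 and 1.36. The cone opsin kinase GRK7 was lower (-1.28 and -1.26), as were the cone channel subunit CNGA3 (-1.05 and -0.996), the retinol carrier RBP4 (-1.76 and -1.78) and the clock gene PER3 (-1.18 and -1.29). Under the table's labels, the same EGR1 arrays read as higher under violet than normal light, by 1.44 in covered and 1.22 in uncovered eyes, with goggle differences of -0.37 under normal and -0.15 under violet light.

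Of 4807 genes, 16 were at least 2-fold higher and 16 at least 2-fold lower in covered eyes in both lights. Over all 35407 passing probes, named or not, the counts were 92 and 55. Among named genes they were 10 and 20 with quantile normalization, 9 and 8 after normexp background correction and 39 and 1 with the table's labels. Genes with both covered pools at least 2-fold above both uncovered pools numbered 13, and 9 lay the other way. The diagonal split of the arrays, which matches neither goggles nor light, gave 0 and 2. The light split gave 1 with both violet-light pools above and 25 with both below. The goggle total of 22 thus did not exceed the 26 for light. Across genes, which are not independent replicates, the goggle differences in the 2 lights correlated with r = 0.588 (Spearman 0.647), and 74.7% had the same sign. These differences share no array, but both covered pools were also dimmer than both uncovered pools before scaling. Neither the agreement nor the counts for goggles were tested apart from that.

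Of the 16 higher genes, 7 belonged to the striated muscle list, which has 17 measured members. They included the fast troponin TNNC2 (6.56 under normal and 3.46 under violet light), the myosin heavy chain MYH1B (5.66 and 2.08), the troponin TNNT3 (5.29 and 1.84) and MYH1C (4.28 and 1.91). The myosin light chain MYL10, outside the list, differed by 7.24 and 3.70, MUSTN1 by 4.06 and 1.51, MYH1A by 4.38 and 1.75, MYL3 by 4.00 and 1.28 and the cardiac actin ACTC1 by 3.72 and 1.23. The fast myosin heavy chains are near-identical copies, so their separate values are uncertain. The 2 probes of ACTC1 differed in their mean goggle difference, 0.57 and 2.47. Without the muscle and lens lists, 9 genes were higher and 16 lower in both lights. The 9 still include MYL10 and MUSTN1, which lie outside these lists, so the count is not free of muscle genes.

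The lower genes came from several groups. The interferon-induced gene IFI6 was lowest (-5.40 and -2.72), and 10 of 12 measured members of the interferon list were lower under normal light, with a median of -0.72, and 9 under violet light, with a median of -0.21 (-0.385 and -0.070 after normexp correction). The list was also lower under violet light, with medians of -0.665 in uncovered and -0.21 in covered eyes (-0.432 and -0.125 after normexp correction). Most members were thus highest in the uncovered normal-light pool, whose array correlated least with the others. The arterial gap junction gene GJA5 differed by -2.15 and -2.16, the prostaglandin D synthase HPGDS by -1.70 and -2.35, the prolactin-like gene PRLL by -1.53 and -1.55 and the complement protease C1S by -2.99 and -1.47. The galectin LGALS1A differed by -1.28 and -1.67. The ion exchanger SLC9A9 differed by -1.26 and -1.41, but its 2 probes disagreed, with mean goggle differences of -1.34 and 0.12.

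Among genes of light detection, the phototransduction list (21 members) had a median of -0.45 under normal light, below all 10000 random lists, and -0.15 under violet light (percentile 0.02). Only GRK7 in it was at least 2-fold lower in both lights, since CNGA3 fell just short under violet light. The nuclear receptor NR2E3 differed by -1.18 and -0.65 and the cone phosphodiesterase PDE6C by -0.88 and -0.62, while RXRG was higher by 0.78 and 0.25. Of 7 opsins, 6 were higher in covered eyes in each light, with medians of 0.40 and 0.33. The melanopsin OPN4 was higher by 0.66 and 0.49, and the green pigment OPN1MSW by 0.34 and 0.54. In the clock list, ASMT, the last enzyme of melatonin synthesis, differed by -1.09 and -0.80, NPAS2 by 0.66 and 0.79 and NFIL3 by 0.59 and 0.81. The other 14 measured members of the immediate-early list stayed under 2-fold in both lights, among them FOS at 0.31 and 0.08 and CYR61 at -0.25 and -0.49.

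The limma fit with light as the pair called none of 4807 genes at an adjusted p of 0.05, with 910 genes at an unadjusted p of 0.05 against 240 from chance. The unadjusted count was 325 with the table's labels and 363 in the authors' table. The fit's error term had 1 residual degree of freedom and came from no replicate pools. With both covered pools also dimmer before scaling, the excess over 240 cannot be ascribed to goggles. The lowest adjusted p of the limma fit was 0.219, for GJA5 (-2.15, SE 0.113, lower in 2 of 2 lights). EGR1 had -1.33 with an SE of 0.126 and an adjusted p of 0.256, lower in 2 of 2 lights. The lack of calls does not show that no gene changed 4-fold, since TNNC2 (5.009) and IFI6 (-4.06) were not called either. With a variance trend limma called 64 genes, and with median scaling 241.

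**Figure D2:**
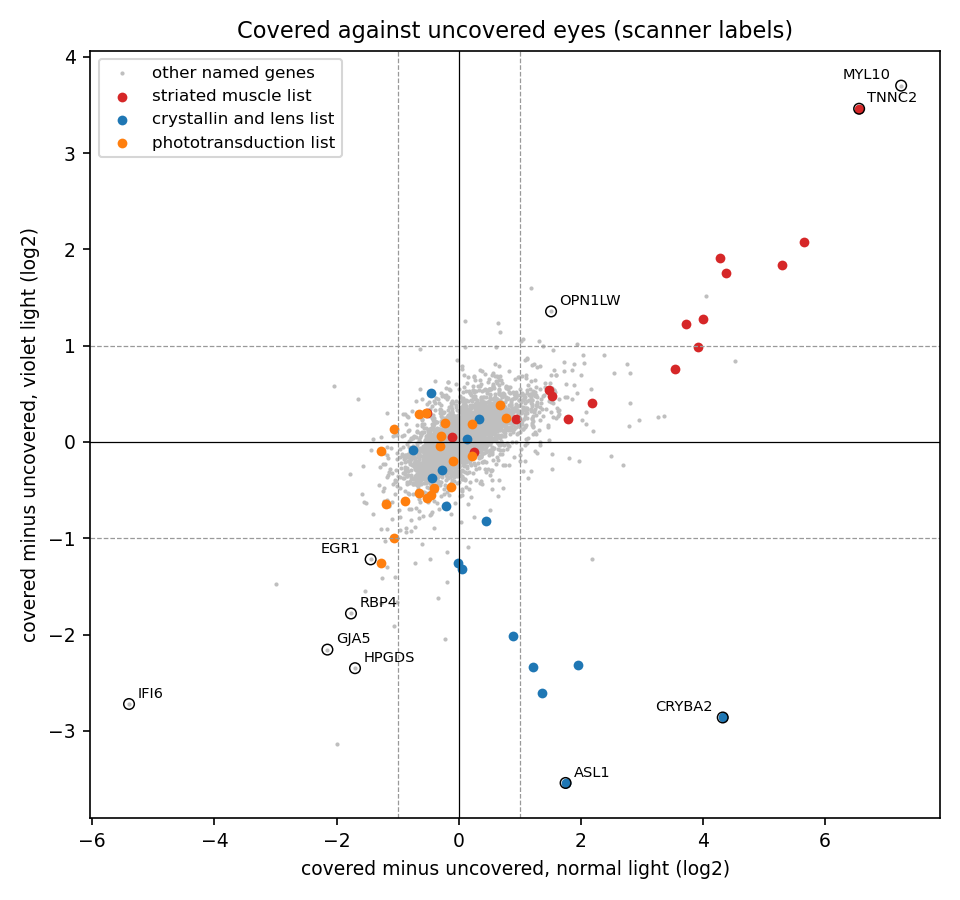
Log2 difference covered minus uncovered under normal light (horizontal) and violet light (vertical), 1 point per gene, with dashed lines at 2-fold. Several muscle genes lie at the upper right (TNNC2 at 6.56 and 3.46). Several crystallins, but not all, are higher under normal and lower under violet light (CRYBA2 at 4.32 and -2.86). EGR1, RBP4, GJA5 and IFI6 lie at the lower left. Under the authors' table the axes read normal minus violet light in covered and in uncovered eyes.

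Under normal light alone, 226 genes were at least 2-fold higher and 68 lower in covered eyes, against 3521 and 386 over all 35407 probes. After MYL10, TNNC2, MYH1B and TNNT3 came TOLLIP, an adaptor of Toll-like receptor signalling, at 4.52. Its other probe disagreed, with mean goggle differences of 0.20 and 2.68 for the 2 probes. Among the lowest genes were IFI6, C1S, GJA5 and the interferon-induced IFI27L2 (-1.78). Of the fibroblast and matrix list, 10 of 22 members were higher and 12 lower (median -0.04), with TNC, POSTN and OGN higher by 2.76, 2.05 and 2.03. That median was 0.472 with the mean of probes, 0.121 after normexp correction and -0.366 with median scaling. The hexokinase HK2 was higher by 1.40 and the vascular growth factor VEGFA by 1.36. The dopamine-synthesis enzyme TH was lower (-1.17), and so were MAFA (-1.27) and CNGA1 (-1.06) of the phototransduction list. Of the striated muscle list, 13 of 17 members were at least 2-fold higher, with a median of 3.54 (2.318 with the mean of probes and 2.698 after normexp correction).

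The direction of the many smaller differences under normal light depended on the scaling. The counts were 118 higher and 139 lower with quantile normalization, 128 and 122 with cyclic loess and 103 and 208 with median scaling, which moved the median of all genes to -0.30. After normexp correction they were 279 and 31. This comparison contains the array that correlated least with the others, and on it probes of one gene disagreed most (270 of 3125 probe pairs at least 2-fold apart). It compares normal with violet light in covered eyes under the table's labels.

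Under violet light alone, 19 genes were at least 2-fold higher and 33 lower in covered eyes, with 14 and 36 after quantile normalization, 14 and 41 after median scaling and 11 and 15 after normexp correction. Over all 35407 probes the balance was the other way, with 139 higher and 112 lower. MYL10 and TNNC2 led the higher genes. The lowest were crystallin genes, namely ASL1 (-3.54), CRYBA2 (-2.86) and CRYBB1 (-2.61), together with IFI6 and HPGDS. In the crystallin and lens list, 8 of 16 members were at least 2-fold lower, with a median of -1.03 (-0.594 after normexp correction). The melanin-synthesis gene TYR was lower (-1.22). In the striated muscle list, 7 of 17 members were at least 2-fold higher, with a median of 0.76. Only 13 of 3125 probe pairs disagreed 2-fold here. Under the table's labels this comparison is normal minus violet light in uncovered eyes.

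The next question was what differed between violet and normal light, whatever the goggle. Light separates 2 sets of chicks, and whether their buttons held unequal shares of choroid was not tested. Several genes of blood vessels and connective tissue, though not most members of those lists, and 2 type IV collagens were at least 2-fold lower under violet light in both eyes. The endothelial transcription factor SOX18 differed by -2.80 in uncovered and -1.99 in covered eyes, VE-cadherin (CDH5) by -1.51 and -1.85, and the ETS factor FLI1 by -1.42 and -1.78. The basement membrane collagens COL4A2 and COL4A1 differed by -2.24 and -1.86, and by -2.13 and -1.77. EGR1 lay at 0.15 in uncovered and 0.37 in covered eyes. Under the table's labels these contrasts become uncovered minus covered eyes, so that SOX18 and the collagens would be higher in covered eyes.

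In all, 39 of 4807 genes were at least 2-fold lower under violet light in both eyes, and 1, CALCA, was at least 2-fold higher (1.69 and 1.15). The counts were 13 lower and 0 higher after normexp correction, 12 and 0 in the brighter probes alone, and 16 and 16 with the table's labels. Over all 35407 probes, 142 were lower and 7 higher. The paired eyes come from the same chicks, so they are no independent repeat of the light. Genes with both violet-light pools at least 2-fold below both normal-light pools numbered 25, and 1 lay above. Across genes the 2 light differences correlated with r = 0.281 (Spearman 0.146), and 53.4% had the same sign.

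In the endothelium list, 4 of 8 measured members (SOX18, SOX17, CDH5 and LYVE1) were at least 2-fold lower in both eyes. The list medians were -0.81 in uncovered and -0.66 in covered eyes, and -0.46 and -0.43 after normexp correction. SOX17 differed by -1.93 and -1.26 and LYVE1 by -1.44 and -1.19, while KDR differed by -0.11 and -0.14. In the fibroblast and matrix list, 5 of 22 were 2-fold lower in both, with medians of -0.64 and -0.92, both below all 10000 random lists, and -0.34 and -0.56 after normexp correction. Examples are the fibrillar collagen COL3A1 (-1.37 and -1.45), COL6A2 (-1.40 and -1.09) and the proteoglycan DCN (-1.26 and -1.21). All 5 measured smooth muscle and pericyte genes were lower in both eyes (medians -0.97 and -0.99), with MYH11 at -1.63 and -0.99 and ACTA2 at -1.002 and -1.212. The erythroid list was lower by a smaller amount, with medians of -0.33 and -0.25 (-0.12 and -0.21 after normexp correction). The striated muscle list had a median of -2.15 in covered eyes (-1.397 with the mean of probes) but -0.13 in uncovered eyes, which became 0.07 after normexp correction.

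Other genes lower in both eyes were the biotin-binding protein avidin (AVD, -2.003 and -2.407), the cytokine IL15 (-1.78 and -2.12), the aminopeptidase ANPEP (-1.68 and -2.93), EMP1 (-1.51 and -2.35) and the interleukin receptor IL1RL1 (-1.50 and -1.71). The probes of ANPEP ranged from -2.31 to -0.41 in their mean light difference, those of FLI1 from -1.60 to -0.64 and those of COL4A1 from -1.982 to -1.195. Higher in both eyes, below 2-fold, were the phosphatase DUSP4 (0.85 and 0.79), the melatonin receptor MTNR1A (0.78 and 0.67), the transcription factor CEBPB (0.70 and 0.65) and the receptor gene PRLHR (0.80 and 0.71). The growth factor BMP4 reached 0.59 and 1.05, and the neuropeptide genes UTS2B and SST1 reached 0.73 and 0.56, and 0.56 and 0.65. FANCB (0.71 and 0.95) and the acetylcholine receptor gene CHRND (1.01 and 0.58) complete the 10.

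**Figure D3:**
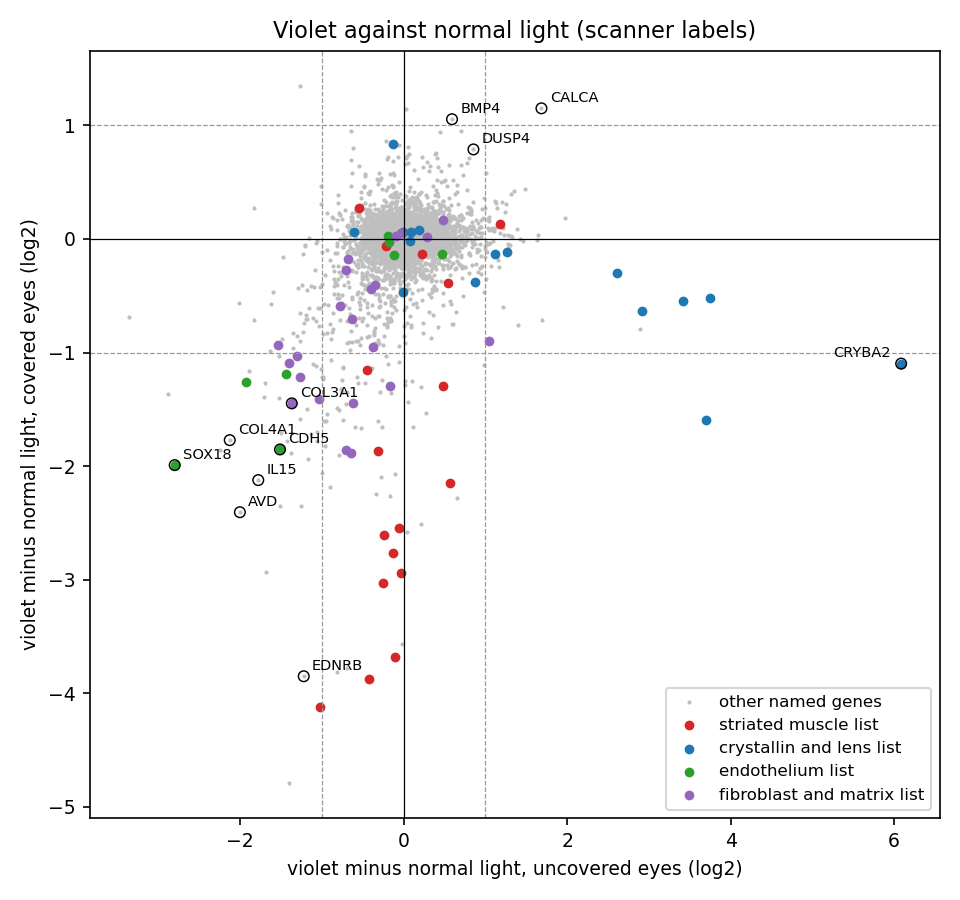
Log2 difference violet minus normal light in uncovered eyes (horizontal) and covered eyes (vertical), 1 point per gene, with dashed lines at 2-fold. Several endothelial and matrix genes lie at the lower left (SOX18 at -2.80 and -1.99). Several crystallins lie at the right (CRYBA2 at 6.09 and -1.10) and several muscle genes at the bottom (TNNC2 at -1.03 and -4.12). Under the authors' table the axes read uncovered minus covered eyes under violet and under normal light.

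In uncovered eyes, 59 genes were at least 2-fold higher and 81 lower under violet light. Over all 35407 probes the balance was the other way, with 1129 higher and 365 lower. For genes the counts were 34 and 112 with quantile normalization and 28 and 32 after normexp correction. Crystallins led the higher genes, with CRYBA2 at 6.09, CRYAA at 3.75, ASL1 at 3.70, CRYBB1 at 3.42 and CRYBB3 at 2.92, and 8 of 16 members of their list were at least 2-fold higher. IFI6 (-3.36), C1S (-2.89), SOX18 and the type IV collagens were lowest. The lipid carrier APOA1, an eye-growth candidate, differed by -1.49. The comparison again contains the array that stood apart (85 of 3125 probe pairs at least 2-fold apart). By the table's labels it is uncovered minus covered under violet light.

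In covered eyes, 4 genes were at least 2-fold higher and 109 lower under violet light, against 35 and 425 over all 35407 probes. Among the 4 higher genes were CALCA (1.15), TH (1.14) and BMP4 (1.05). The lowest were the fibrinogen-like gene FGL2 (-4.79), TNNC2 (-4.12), TNNT3 (-3.88), the endothelin receptor EDNRB (-3.85) and OCM3 (-3.82), an oncomodulin gene. Of the striated muscle list, 12 of 17 were at least 2-fold lower, and of the fibroblast and matrix list 9 of 22, among them POSTN and MMP2 (-1.88 and -1.85). Without the muscle and lens lists, which do not hold MYL10, 4 were higher and 95 lower, and after normexp correction 0 and 55. Only 19 of 3125 probe pairs disagreed 2-fold. On the table's labels this is uncovered minus covered under normal light.

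The last question was whether the goggle difference itself differed between lights. The most positive light-by-goggle differences, meaning a goggle difference higher under violet than normal light, included those of IFI6 (2.68), the Wnt receptor FZD10 (2.096), the retinal progenitor factor FOXN4 (1.60), C1S (1.52), DLX3 (1.49), IFI27L2 (1.45) and the transporter SLC38A4 (1.42). The most negative belonged to crystallins and muscle genes, namely CRYBA2 (-7.18), ASL1 (-5.29), CRYAA (-4.27), CRYBB1 (-3.96), CRYBB3 (-3.56), MYH1B (-3.58) and MYL10 (-3.54), and to TOLLIP (-3.68). EGR1 lay at 0.22.

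Of 4807 genes, 34 had a light-by-goggle difference of at least 2-fold in the positive and 119 in the negative direction. These were 64 and 78 with quantile normalization, 84 and 74 with median scaling and 9 and 75 after normexp correction. Over all 35407 probes they were 271 and 1478. In the crystallin and lens list 9 of 16 members passed, all negative, and in the striated muscle list 12 of 17. The interferon list had a median of 0.50, above all 10000 random lists. The phototransduction members CNGA1 (1.195) and MAFA (1.18) were at least 2-fold positive. Of the dopamine list, TH alone passed (1.11). Each of these is 1 value per gene with no residual degrees of freedom, so none was tested, and each includes the array that stood apart.

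**Figure D4:**
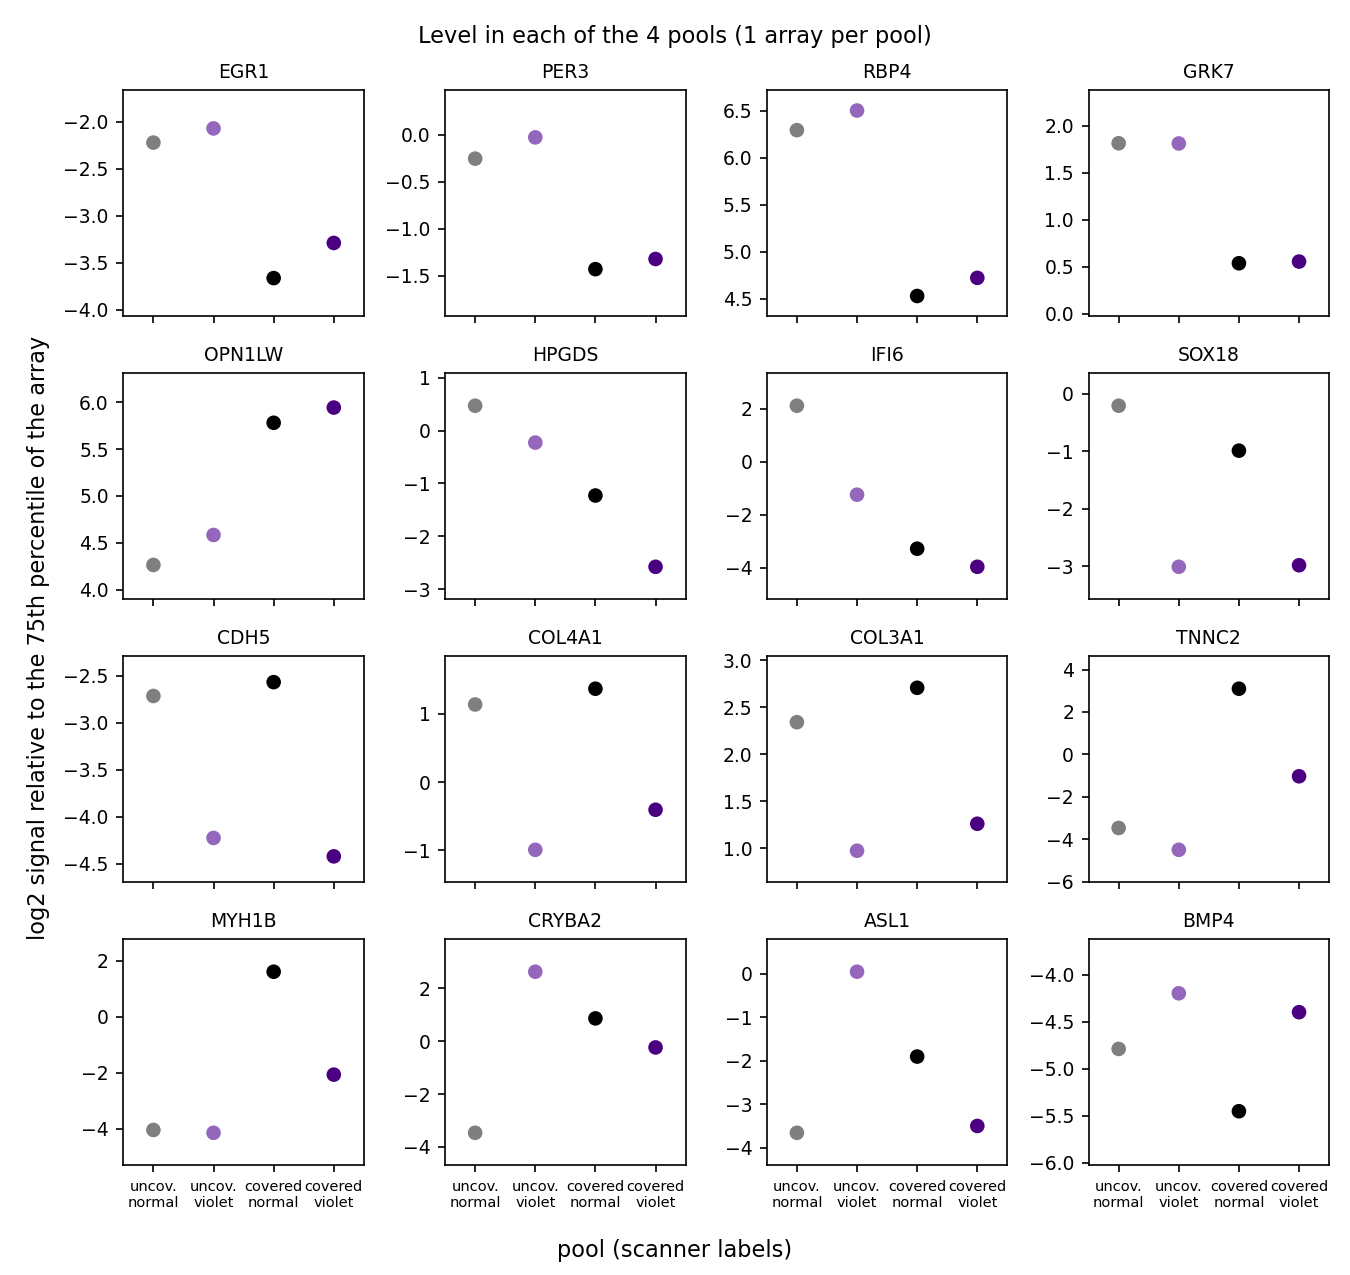
Log2 signal relative to the array's 75th percentile for 16 genes in the 4 pools, 1 point per pool with no replicates, under the scanner labels. EGR1 lay at -2.22 and -2.07 in the uncovered pools and at -3.66 and -3.29 in the covered pools, SOX18 and CDH5 were low in both violet-light pools, TNNC2 was highest in the covered normal-light pool (3.10) and CRYBA2 in the uncovered violet-light pool (2.62); the labels of the first and last pool are exchanged in the authors' table.

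Some genes were well above background on only one side. On the covered side alone were 5 genes, with the slow myosin MYH7B at least 8.10-fold higher, myoglobin (MB) at least 7.21-fold, the muscle protein gene CSRP3 at least 6.23-fold, DHRS7C at least 2.502-fold and the vascular growth factor receptor FLT1 at least 2.15-fold. On the uncovered side alone were 27 genes, led by the interferon-induced MX1 (at least 4.87-fold), the glutathione transferase GSTA3 (at least 4.16-fold), SMIM8 (at least 3.06-fold), DLX5 (at least 2.05-fold) and ANKRD22 (at least 1.43-fold). On the normal-light side alone were 9 genes, with SMYD1, a muscle methyltransferase, at least 1.90-fold higher, then MEOX2 at 1.86, BST1 at 1.70, THPO at 1.67 and TES at 1.55. None was on the violet-light side alone. Detection was uneven, with more probes well above background in the uncovered (85.97% and 84.43%) than in the covered pools (83.75% and 83.07%). In each eye the normal-light pool had the larger share. The lowest signal well above background was also lower in the uncovered (-7.405 and -6.934) than in the covered pools (-6.579 and -6.562). The unequal counts per side were not tested apart from that. With the labels of the table, the covered side becomes the normal-light side, and the normal-light side becomes the covered side.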

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

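Of the tests below, those on the muscle genes and on pairs of probes were chosen only after the result was seen, as were the smaller set of muscle members, the interval asked of their SD, the comparison of chromosome W genes with other genes and the mention of BFSP2. So was the rule that both differences of a gene had to reach 2-fold in opposite directions to be listed.

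Several genes differed in opposite directions between lights or between eyes, and none of these differences could be tested with 1 array per group. For goggles, CRYBA2 was at 4.32 under normal and -2.86 under violet light, ASL1 at 1.75 and -3.54, CRYAA at 1.96 and -2.31, CRYBB1 at 1.36 and -2.61 and CRYBB3 at 1.22 and -2.34. The fibrinogen-like gene FGL2 was at 2.18 and -1.21. For light, CRYBA2 was at 6.09 in uncovered and -1.10 in covered eyes, and ASL1 at 3.70 and -1.59. With the table's labels these values keep their size, with goggles and light exchanged.

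The first pattern weighed is the crossing of labels between the scanner files and the authors' table. Either set of labels may be the wrong one, and a test was sought in genes of chromosome W, whose level in a pool follows its share of female chicks and so should be alike in the eyes of the same chicks. Over 9 such genes, the mean absolute goggle difference was 0.192 and the mean absolute light difference 0.175, a gap of 0.017 with an interval over genes of -0.02 to 0.055. Random lists of as many autosomal genes had a mean gap of 0.085 and an interval of -0.068 to 0.23, so the gap argues for neither set of labels. Both explanations stay open, and a biological reading of any goggle or light difference stays open with them.

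The second pattern is gene groups of another tissue in single pools: striated muscle genes were highest in the covered normal-light pool, and muscle left on the button could account for this, since 13 of 17 measured members were at least 2-fold higher there and 7 in both covered pools. Muscle tissue would keep one ratio between pools, but over the 13 members the log2 ratio of the excess in the covered pools had an SD of 1.62, above the bound of 1 set against it, with an interval over members of 0.769 to 2.14 that includes that bound, and over the 7 with the clearest excess the SD was 0.692, so the test leaves muscle open. The extreme ratios, 5.868 for TPM2 and -0.289 for MYH7, came from members outside the 7 with the clearest excess. ACTN2 (-0.10), MYBPC2 (-0.52) and PVALB (0.26) did not share the excess. MYH7B and MB of the same list, well above background in the covered pools alone, were at least 8.10-fold and 7.21-fold higher there and are not among the 17. A response of the tissue to goggles remains open as well. For the crystallins of the uncovered violet-light pool, lens tissue was argued against by a bound of 0.5 set beforehand: the 3 measured lens genes other than crystallins had a median difference of 0.087, each under the bound, with BFSP1 at 0.09 and MIP at -0.61. The lens gene BFSP2 instead rose with the crystallins, from a log2 signal level of -8.341 in the uncovered normal-light pool to -6.617 in the uncovered violet-light pool. It lay near the limit of detection and was above background in the latter pool alone. A share of lens too small for the other genes to show is thus not excluded, and a response to light stays open.

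The third pattern is that comparisons with the uncovered normal-light pool gave the most genes, 294 for goggles under normal against 52 under violet light. For light the excess among named genes was far smaller, 140 in uncovered against 113 in covered eyes. Over all 35407 probes it was larger, with 3907 against 251 for goggles and 1494 against 460 for light. A scaling that depends on intensity was argued against, because after cyclic loess there were still 4.9 times as many genes under normal as under violet light. A difference between probes of one gene, such as RNA integrity or labelling could bring, went with the data: the lowest count of probe pairs at least 2-fold apart in a comparison with that array was 85 of 3125, against at most 25 among the other arrays. After cyclic loess these were 61 and 22. A biological difference of that pool was not tested apart from this and stays open.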

How the results depend on the processing

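Tests chosen only after the data were seen were the repeat with the table's labels, the table put on the scanner files' labels and the counts without the muscle and lens lists. Counts below are genes at least 2-fold higher and lower out of those measured, and those within 1.5 times the reported count are left out unless their partner moved. As reported, the counts were 226 and 68 for goggles under normal light, 19 and 33 for goggles under violet light, 59 and 81 for light in uncovered eyes and 4 and 109 for light in covered eyes. For both lights together the goggles gave 16 and 16. For both eyes together light gave 1 and 39. The light-by-goggle difference gave 34 and 119. The cause of each change was not tested, except that a looser filter adds dim genes and a stricter one removes them. Signal over background sets a limit, since 4807 of 5294 named genes had a probe well above background on all 4 arrays. No paired analysis was possible because each group has 1 array, apart from the limma fit, in which light pairs the eyes. No array could be left out.

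With quantile normalization, they were 118 and 139 for goggles under normal light, 34 and 112 for light in uncovered eyes, 10 and 20 for goggles in both lights and 64 and 78 for the light-by-goggle difference. Under median scaling, they were 103 and 208 for goggles under normal light, 34 and 117 for light in uncovered eyes, 10 and 24 for goggles in both lights and 84 and 74 for the light-by-goggle difference. With cyclic loess, they were 128 and 122 for goggles under normal light, 38 and 111 for light in uncovered eyes, 10 and 22 for goggles in both lights and 58 and 83 for the light-by-goggle difference. The median of all genes lay at 0.021 for goggles under normal light and -0.010 for light in uncovered eyes as reported, and at -0.302 and -0.183 with median scaling. Median scaling moves all genes of a comparison alike, so its changes of direction describe that shift. With the mean of probes it lay at 0.105 for goggles under normal light.

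After normexp background correction, they were 279 and 31 for goggles under normal light, 11 and 15 for goggles under violet light, 28 and 32 for light in uncovered eyes and 0 and 55 for light in covered eyes. Counts for the combined results were 9 and 8 for goggles in both lights, 0 and 13 for light in both eyes and 9 and 75 for the light-by-goggle difference. With the mean of a gene's probes, the counts were 0 and 35 for light in both eyes.

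With probes well above background on at least 1 array, they were 272 and 112 for goggles under normal light, 50 and 70 for goggles under violet light, 24 and 162 for light in covered eyes and 33 and 29 for goggles in both lights. In the same setting there were 4 and 54 for light in both eyes and 77 and 175 for the light-by-goggle difference. With no filter on dim probes, they were 326 and 127 for goggles under normal light, 76 and 80 for goggles under violet light, 111 and 135 for light in uncovered eyes and 44 and 181 for light in covered eyes. The same setting gave 38 and 31 for goggles in both lights, 7 and 56 for light in both eyes and 105 and 228 for the light-by-goggle difference. In the brighter probes alone (those above the median of the passing probes, so fewer genes), they were 53 and 32 for goggles under normal light, 4 and 10 for goggles under violet light, 17 and 26 for light in uncovered eyes and 0 and 30 for light in covered eyes. Those probes gave 3 and 6 for goggles in both lights, 0 and 12 for light in both eyes and 8 and 27 for the light-by-goggle difference.

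In the authors' value table on its own labels, they were 108 and 5 for goggles under normal light, 114 and 32 for goggles under violet light, 35 and 14 for light in uncovered eyes and 137 and 114 for light in covered eyes. The table gave 48 and 1 for goggles in both lights, 19 and 10 for light in both eyes and 63 and 73 for the light-by-goggle difference. With the scanner values on the table's labels, they were 109 and 4 for goggles under normal light, 81 and 59 for goggles under violet light, 33 and 19 for light in uncovered eyes and 68 and 226 for light in covered eyes. These labels gave 39 and 1 for goggles in both lights and 16 and 16 for light in both eyes. With the value table on the scanner files' labels, they were 114 and 137 for goggles under normal light, 32 and 114 for light in uncovered eyes, 10 and 19 for goggles in both lights and 63 and 73 for the light-by-goggle difference. Without the striated muscle and lens lists, they were 12 and 25 for goggles under violet light and 9 and 16 for goggles in both lights. MYL10 and MUSTN1 lie outside those lists and remain in these counts.

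The limma fit of the goggles called 0 genes as reported (910 at an unadjusted p of 0.05, 240 expected by chance, against 325 with the table's labels and 363 in the authors' table), 64 with a variance trend, 241 with median scaling and 5 in the brighter probes. It called 0 under the other 11 settings, among them the model without light, the value table and the table's labels. At median scaling the prior had infinite degrees of freedom, so all genes shared one variance. The excess over 240 cannot be ascribed to goggles, for the reasons given with the fit. Over the named genes, 1657 of 2355 values under another scaling, background correction or probe rule lay within 0.209 of the reported log2 difference, 698 moved further and 0 of those at least 2-fold changed sign. That 0.209 is the robust SD of the light-by-goggle difference over genes, scaled to 1 difference, and stands in for a spread between replicates. A sign change at 2-fold needs a shift above 1 on the log2 scale. Median scaling moved the median of all genes to -0.302 for goggles under normal light. The named genes were also mostly chosen for large differences, so the lack of sign changes says little about robustness. Of 306 list medians with quantile normalization, cyclic loess or the mean of probes, 292 lay within it, 14 moved further and 0 of those at least 2-fold changed sign. Only medians of the striated muscle and crystallin lists were at least 2-fold. The 306 are medians of the mean goggle, mean light and light-by-goggle differences, not of single comparisons. Some of the latter moved further. For goggles under normal light, the mean of probes moved the fibroblast and matrix median from -0.042 to 0.472 and the retinoic acid median from -0.391 to 0.141. Median scaling and normexp are not in the 306, and normexp moved the endothelium medians for light from -0.81 and -0.66 to -0.46 and -0.43.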

Other observations

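None of the values here was tested, and no hypothesis is offered for them. They describe gene lists that the comparisons above do not cover, under the scanner labels, with goggles as covered minus uncovered and light as violet minus normal. On the table's labels, goggle values read as normal minus violet light and light values as uncovered minus covered.

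For goggles, horizontal cell genes (5 members) lay at -0.46 under normal and -0.27 under violet light, with CALB1 at -0.69 and -0.30 and TFAP2B at -0.46 and -0.27. Myelin and oligodendrocyte genes (8 members) lay at -0.27 and -0.18, the first of which was -0.48 with quantile normalization and -0.14 with the mean of probes, with SOX10 at -0.78 and -0.35 and MBP at -0.42 and -0.48. Heat shock genes (15 members) lay at -0.15 and -0.21, the first of which was -0.05 with the mean of probes, with HSPA2 at -0.47 and -0.76, HSPB9 at -0.63 and -0.53 and HSPH1 at -0.46 and -0.54, while HSPB2 was at 2.95 and 0.22. The amacrine cell list (17 members) lay at -0.225 and -0.05, the second of which was -0.16 with quantile normalization and 0.009 after normexp correction, with the neuropeptide NPY at -0.66 and -0.59. The retinoic acid list (12 members) lay at -0.39 under normal light, which became 0.14 with the mean of probes. Under violet light it lay at 0.095, with 8 members higher and 4 lower.

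Cholesterol and lipid genes (23 members) lay at 0.15 and 0.17, the first of which was 0.43 with the mean of probes, with ELOVL2 at 0.92 and 0.65. Müller glia genes (12 members) lay at 0.27 and 0.02, which were 0.08 and -0.07 with quantile normalization. Ganglion cell genes (12 members) lay at 0.12 and 0.09 (0.065 and 0.050 with quantile normalization), and visual cycle genes (15 members) at 0.17 and 0.02, with RPE65 at 0.62 and 0.44 and RDH10 at -0.63 and -0.42. Of single genes in other lists, the bipolar cell gene VSX1 was higher by 0.57 and 0.71, NOS2 by 0.54 and 0.69 and the metallothionein MT4 by 0.70 and 0.65.

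For light, ribosomal protein genes were higher under violet light in 44 of 45 members in uncovered eyes (median 0.335) and in 45 of 45 in covered eyes (0.106). These medians were smaller with quantile normalization (0.151 and 0.037) and cyclic loess (0.221 and 0.027). Pigment cell genes (13 members) lay at -0.10 and -0.28, with 12 of 13 lower in covered eyes, among them EDNRB (-3.85), TYR (-1.14) and TYRP1 (-0.69). The TGF-beta and BMP list (24 members) lay at -0.12 and -0.16, the first of which ranged from -0.205 (quantile normalization) to -0.079 (mean of probes), with TGFBI at -0.98 and -1.60 and CHRDL1 at -1.11 and -0.69.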
